A study of Mus musculus with 6 samples.

How the data were processed

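MBD-seq was done on genomic DNA of 6 mouse lungs, 3 transgenic and 3 wild type, which the labels give as biological replicates, and methylated DNA was captured with a commercial methyl-binding-domain kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The genotype label of transgenic replicate 2 is spelled differently from those of replicates 1 and 3, and the title was followed. The labels give neither sex nor founder line for these animals.

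Reads were aligned with Bowtie to the mouse build mm10, and DiffBind and edgeR were used for the differential regions, per the submitters' processing notes, which give no versions. Peaks were called for each library separately, and their names in the deposited lists are those MACS writes, whose version and settings are not given in the sources used here. The score of each peak in the deposited lists is the authors' peak caller's own value, starts at 50 in every list and was used to rank, filter and describe peaks and, as the median per library, compared between groups once. It is not scaled between libraries. The authors' deposited table of 407 differential regions gives read concentrations and the fold on a log2 scale, and the log2 fold equals the transgenic minus the wild-type concentration in every row to within 1.07e-14. The p-value and FDR of each region are the authors' own, per the file headers. Distances in bp to genes and CpG islands come from the authors' 2 deposited annotation tables. The normalization of the concentrations is not given in the sources used here, so a difference in capture efficiency or depth between libraries can remain in the folds.

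The FDR and p of the authors' deposited table imply 92205 tested regions, the same number as the merged regions with a peak in 3 or more lists, and all 407 differential regions equal merged regions. Starts of the differential regions are printed as the table gives them, which are the 0-based starts of the peak lists. Starts of regions taken from the peak lists are 1-based. Peaks of the 6 lists were merged where they shared or touched at 1 bp, a reading chosen after the table's regions were seen to equal it. A region was group-specific when all 3 libraries of a group had a peak and no library of the other group had one.

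Gene spans came from a RefSeq table of the same assembly with 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 are protein-coding. That table gives no strand, so in place of the promoters planned before the data were examined both ends of a gene, plus or minus 1000 bp, were used for the peak lists, while transcription starts of differential regions came from the authors' annotation, which gives strand. The authors' annotation names genes by Ensembl identifiers, and 375 of 488 were matched to a symbol by a reciprocal overlap of gene spans of 0.5 or more. Exons and introns were not resolved. The CpG content of peaks was planned and not computed, because no genome sequence was used here.

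Library values were compared by two-sided exact permutation tests of the difference of group means, which cannot go below p = 0.10 with 3 against 3. Shares of regions were compared by Fisher's exact test, and Benjamini-Hochberg adjustment was made over the 15 gene groups, over the 42 tests of chromosomes, and over the 90 tests of gene groups against other genes in each library. The tests of chromosomes, of regions inside genes, of X genes and of gene groups against other genes were added after the data were seen. The background for gene groups was the genes overlapping or nearest to a merged region with peaks in 2 or more lists. The intervals are 95% exact binomial intervals and cover counting error only. Read depth per library is unknown, and list length stands in for it only in part.

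The regions named were the 12 with the largest absolute fold in each direction, members of 15 gene groups with a differential region (at most 4 per group), Sftpc and Dnmt3b, and the 6 group-specific regions per direction at a gene end with the highest lowest score. The groups were markers of alveolar type 2, alveolar type 1, airway, endothelial, immune and mesenchymal cells, tumour suppressors, lung oncogenes, homeobox and T-box genes, imprinted genes, germline genes, clustered protocadherins, olfactory and vomeronasal receptors, methylation machinery and Wnt signalling. Alternatives were an equal number of top-scoring peaks per list (30640), peaks at or above the pooled median score (96.3), windows of 500 and 2000 bp, protein-coding genes alone, other overlap and merging rules, a stricter FDR, a fold threshold, other backgrounds, a block for the replicate number, and leaving out each library in turn. The count of group-specific regions and the gene group test were tested on simulated data, where 200 of 200 planted regions among 166001 and 1 of 1 planted gene group among 49943 genes were recovered. The planted regions had the exact group pattern without noise, and the planted gene group was strongly enriched. Their recovery therefore checks the code and says nothing of sensitivity in the real data. The simulated libraries had the real shares of regions with a peak but were otherwise independent. In them 7067 unplanted regions were also transgenic-specific (7030 were predicted), against 2987 in the real lists. Wild-type-specific regions were not counted in the simulated lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.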

Results

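Methylated DNA of whole mouse lung was captured with a methyl-CpG-binding domain protein and sequenced (MBD-seq), so that a peak marks a place where methylated fragments were enriched. The study had 6 libraries from separate animals aged 12 to 16 months, 3 of them wild type and 3 transgenic. The transgene was a deletion variant of DNMT3B, a de novo DNA methyltransferase, under the promoter of Sftpc, the surfactant protein C gene of alveolar type 2 cells. The comparison asks where lung DNA methylation differed between transgenic and wild-type animals. Each library had its own peak list, and the authors' deposited table of differential regions gave 1 fit of the 3 transgenic against the 3 wild-type libraries. Read depth was unknown, and the number of peaks and the sequence they covered are given in its place.

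The region with the largest change lay in Dnmt3b-ps1, a copy of Dnmt3b that is also named Dnmt3c and is annotated as a pseudogene. In the authors' deposited table it covered positions 153713425 to 153713719 of chromosome 2 (mm10) and was higher in the transgenic mice, with a log2 fold of 3.51 and an FDR of 1.27e-05. Its wild-type concentration of 0.66 (log2) was the lowest in the authors' deposited table and the same for 3 regions, so this fold depends on how low counts were handled. Another region lay at the end of the same gene, from 153729520 to 153729971 and upstream of Mapre1, a microtubule-end binding protein gene. It was 4.46-fold higher in the authors' deposited table (log2 fold 2.16, FDR 0.00134). At both places all 3 transgenic lists had a peak and no wild-type list had one. The peak scores, which are the authors' own, were 558, 248 and 169 in transgenic replicates 1, 2 and 3 at the region inside the gene and 459, 186 and 185 at the region at its end.

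**Figure D1:**
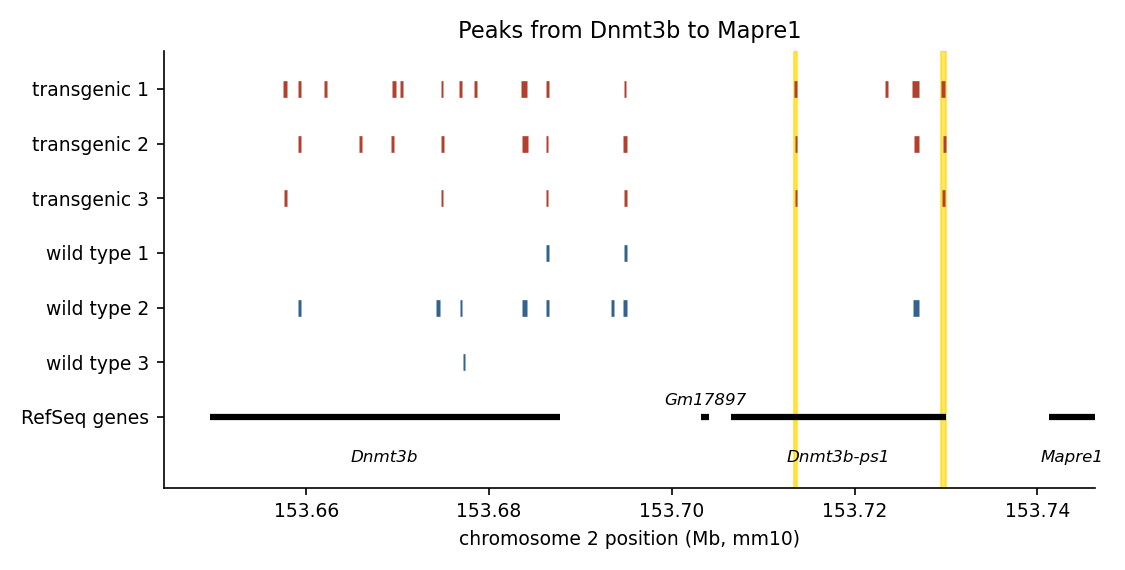
Peaks of the 6 libraries from Dnmt3b to the start of Mapre1, by position on chromosome 2 (Mb, mm10), with RefSeq gene spans below (Mapre1 runs past the right edge) and the 2 differential regions of the authors' deposited table in yellow. At both regions the 3 transgenic libraries have a peak and the 3 wild-type libraries have none.

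The mouse genes named after the transgene's promoter and enzyme had peaks in both groups. The species of the transgene's own sequences is not given in the sources used here, so whether its reads can align to these genes or to Dnmt3b-ps1 is unknown. Sftpc (chromosome 14, 70520941 to 70524081) had a peak within the gene in all 6 libraries, with a highest score of 298, 197 and 166 in the transgenic lists and 85.2, 163 and 54.0 in the wild-type lists. Dnmt3b (chromosome 2, 153649411 to 153687730) held 10, 6 and 3 peaks in the transgenic lists and 1, 5 and 1 in the wild-type lists. Neither gene had a differential region in the authors' deposited table.

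Of 407 regions in the authors' deposited table, 304 were higher and 103 lower in the transgenic mice, at a largest listed FDR of 0.0996. The higher regions were wide and strongly captured, with a median width of 1192 bp and a median wild-type concentration of 5.95 (log2) in the authors' deposited table, against 568 bp and 4.30 for the lower regions. The median log2 fold was 0.63 (1.54-fold) for the higher regions and -1.60 for the lower regions in the authors' deposited table. At the 0.0498 level, which is the largest FDR listed divided by 2, the authors' deposited table held 151 higher and 38 lower regions. An absolute log2 fold of 1 or more was reached by 62 higher and 85 lower regions of the authors' deposited table, so that the larger group by count depended on the size of change asked for. All these regions were picked by FDR, and their median concentration over all libraries was 6.28 for higher and 3.68 for lower regions (log2). The folds of the 2 groups are therefore not compared at like concentration, and do not show that losses were larger than gains.

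**Figure D2:**
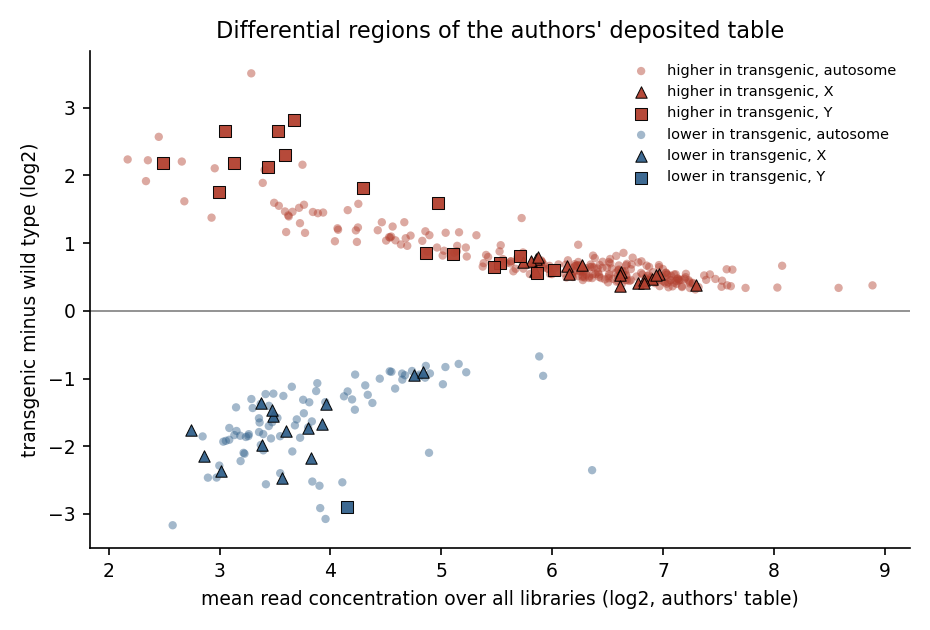
The 407 differential regions of the authors' deposited table, with the mean read concentration over all libraries (log2) on the x axis and the log2 difference of transgenic minus wild type on the y axis, 1 symbol per region, circles for autosomes, triangles for X and squares for Y. The 304 higher regions gather at high concentration and small fold (median 0.63), and the 103 lower regions at low concentration and larger fold (median -1.60). Their folds are thus not compared at like concentration.

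Among the 12 higher regions with the largest fold, 6 lay on chromosome Y, with log2 folds from 2.18 to 2.82 in the authors' deposited table. They included a region at 67023938 to 67024332, downstream of Ssty2, a multicopy spermatid gene, with a log2 fold of 2.19 and an FDR of 0.0861 in the authors' deposited table. On the autosomes, a region inside Slc25a21, a mitochondrial carrier gene (chromosome 12, 56983292 to 56983756), had a log2 fold of 2.57 in the authors' deposited table (FDR 0.0522). On chromosome 17, a region inside Gtf2a1l, a germ-cell transcription factor gene, and a region over the start of Lhcgr, the luteinizing hormone receptor gene, had log2 folds of 2.23 and 2.20 in the authors' deposited table (FDR 0.0678 and 0.0861). The regions of Slc25a21 and Gtf2a1l are the others at that lowest wild-type concentration. The last of the 12 lay upstream of the small gene Gm25094 on chromosome 6, with a log2 fold of 2.22 in the authors' deposited table. At these regions the transgenic lists all had a peak, and the wild-type lists had a peak in at most 1 of 3. At the 6 regions on chromosome Y the scores of transgenic replicate 2 were 53.6 to 65.1, near the lowest score of 50, against 193 to 319 in replicate 1 and 105 to 221 in replicate 3.

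Among the 12 lower regions with the largest fold, the first lay inside Hltf, a helicase-like chromatin remodelling gene (chromosome 3, 20103055 to 20103389), with a log2 fold of -3.17 and an FDR of 0.0104 in the authors' deposited table and a peak in 0 transgenic and 3 wild-type lists. A region upstream of Eno1b on chromosome 18 had a log2 fold of -3.07 (FDR 0.0303), and a region inside the potassium channel gene Kcnh1 on chromosome 1 had a log2 fold of -2.91 (FDR 0.0169), both in the authors' deposited table. Regions inside Asic2, an acid-sensing ion channel gene, and over the end of Tekt1, a tektin gene of cilia, both on chromosome 11, each had a log2 fold of -2.46 in the authors' deposited table. The region in Frmpd3 on chromosome X, from 140278184 to 140278761, had a log2 fold of -2.47 in the authors' deposited table and was the only lower region that overlapped a CpG island. The other 6 lay outside genes in the authors' annotation. It assigned them to Vmn2r-ps139 on chromosome Y, Mir467h, Gm23225, Rps2-ps5, 1700123O21Rik and Mir6393. Their log2 folds were from -2.90 to -2.40 in the authors' deposited table. Of these 12 regions, 7, among them those of Eno1b, Kcnh1 and Tekt1, had a peak in a transgenic list, and at 9 the highest score was that of wild-type replicate 3, the library with the shortest list.

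Chromosome Y held more of the higher regions, and chromosome X more of the lower regions, than their shares of tested regions. On chromosome Y lay 17 of the 304 higher regions of the authors' deposited table (5.59%) against 0.728% of the 92205 merged regions with peaks in 3 or more lists (two-sided Fisher's exact test, adjusted p = 6.49e-09 over 42 tests). Chromosome X had 15 of the 103 lower regions of the authors' deposited table (14.6%) against 3.88% of the merged regions (adjusted p = 0.000223, same test). Among these were regions inside the homeobox gene Rhox2a (log2 fold -2.17) and the splicing factor gene Zrsr2 (log2 fold -2.37) in the authors' deposited table. Neither the 18 higher regions on X (5.92%, adjusted p = 0.507) nor the 1 lower region on Y (0.971%, adjusted p = 0.886) of the authors' deposited table departed from these shares in the same test. These tests take regions, not animals, as units, and regions on 1 chromosome of an animal need not vary independently. Their p therefore does not measure a difference between the 2 groups of animals. Rhox2a and Zrsr2 were chosen after their values were seen. The libraries also differed on these chromosomes. Of 966 protein-coding X genes, 16.7% had a peak within 1000 bp of an end in transgenic replicate 1 (95% exact binomial interval 14.4% to 19.2%) and 11.9% in transgenic replicate 3 (9.93% to 14.1%), below the 28.2% and 18.2% of autosomal genes in the same lists. In transgenic replicate 2 a peak was found at 483 of the 966 X genes, against 25.9% of autosomal genes. In wild-type replicates 1, 2 and 3 the share was 26.3%, 51.7% and 10.7% of X genes against 12.7%, 25.3% and 5.37% of autosomal genes. Chromosome Y held 1.67% and 1.86% of the peaks of transgenic replicates 1 and 3 and 0.599% to 0.911% of the peaks of the other 4 lists. Without chromosomes X and Y, 269 higher and 87 lower regions of the authors' deposited table were left.

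**Figure D3:**
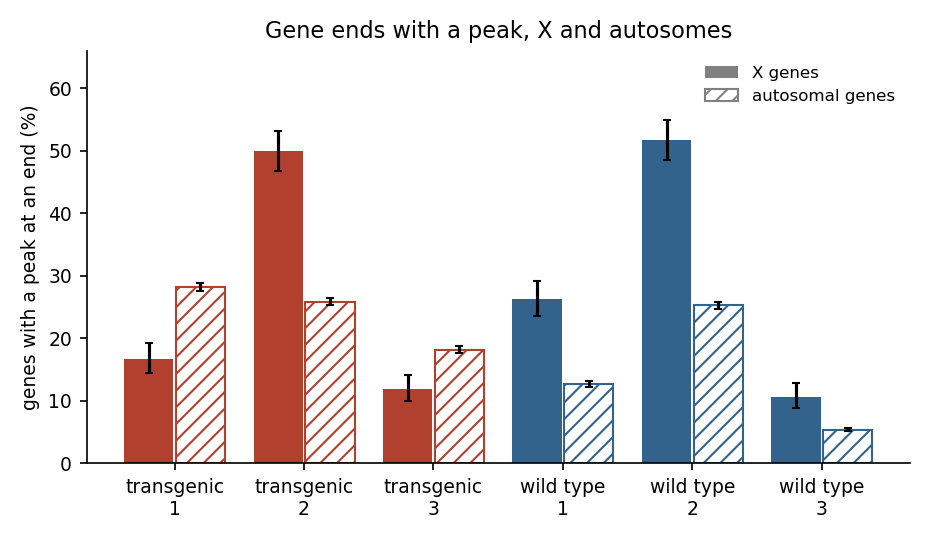
Share of protein-coding genes with a peak within 1000 bp of an end (%), for 966 X genes (filled bars) and 20665 autosomal genes (hatched bars) in each of the 6 libraries, transgenic in red and wild type in blue, with 95% exact binomial intervals as error bars. The X share is below the autosomal share in transgenic replicates 1 and 3 (ratios 0.592 and 0.654) and above it in the other 4 libraries (ratios from 1.93 to 2.07).

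Lower regions lay closer to genes than higher regions. An annotated gene contained or touched 61 of 103 lower regions (59.2%) and 109 of 304 higher regions (35.9%) of the authors' deposited table (two-sided Fisher's exact test, p = 4.64e-05). A transcription start lay within 1000 bp of 11 lower regions (10.7%) and 10 higher regions (3.29%) of the authors' deposited table (p = 0.00759, same test). Among them were the lower regions of Rhox2a, Zrsr2 and the transcriptional repressor gene Bcl6b and the higher regions of Dazl and Lhcgr. Without chromosomes X and Y, Fisher's exact test gave p = 0.236 for the start shares of 6.90% and 3.72%, and p = 0.000116 for the gene shares of 62.1% and 38.3%. CpG islands were overlapped by 14 higher regions (4.61%) and 1 lower region (0.971%) of the authors' deposited table (Fisher's exact p = 0.129). The higher ones included those of Dazl, Pcdha1, the T-cell factor gene Bcl11b and the zinc-finger gene Zfp787. Without X and Y, 13 higher and 0 lower regions overlapped an island (Fisher's exact p = 0.0438). These tests take regions, not animals, as units, and Bcl6b, Bcl11b and Zfp787 were chosen after their values were seen.

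No predefined gene group was enriched for differential regions. Of the germline genes, 1 member carried a region, over the start of Dazl, a germ-cell RNA-binding protein gene (chromosome 17, 50293034 to 50294397), with a log2 fold of 0.68 and an FDR of 0.0416 in the authors' deposited table. Of the developmental homeobox and T-box genes, 2 members had a region assigned to them by the authors' annotation, at a long distance. Downstream of the POU-domain gene Pou3f4 were 2 regions (log2 fold 0.80 and 0.38), at annotated distances of 130875 and 65705 bp. The LIM-homeobox gene Lhx9 had 1 downstream region (log2 fold 0.65) at an annotated distance of 59851 bp. For downstream regions the annotated distance is longer than that to the nearest edge of the gene. The distance to the RefSeq span was 126047 bp for the first Pou3f4 region and 35311 bp for that of Lhx9. The log2 folds of these regions are those of the authors' deposited table. Clustered protocadherins, which are neuronal adhesion genes, had 1 region, in the alpha cluster inside Pcdha1, with a log2 fold of 0.39 in the authors' deposited table. Of the olfactory and vomeronasal receptor genes, 5 had a region assigned to them by the authors' annotation. The 4 with the largest change were Olfr786 (log2 fold 1.17), Olfr15 (-1.02), Vmn1r230 (0.76) and Vmn2r127 (0.57) in the authors' deposited table. The signed annotated distances were -23785, -16687, 18427 and -37783 bp, where a negative value is upstream. The region downstream of Vmn1r230 can lie closer to the gene's nearest edge. The other 11 groups, which were markers of alveolar type 2, alveolar type 1, airway, endothelial, immune and mesenchymal cells, tumour suppressors, lung oncogenes, imprinted genes, methylation machinery and Wnt signalling, had no member with a region in the authors' deposited table. Of 32980 background genes 322 (0.976%) had a region, and these 11 groups had 7 to 43 genes each in that background. A count of 0 is therefore little evidence that their genes were spared. In one-sided Fisher's exact tests of genes against 32980 background genes the smallest p was 0.101, for the homeobox and T-box group with 2 of 55 genes, and all 15 adjusted p were 1. With the nearest RefSeq gene in place of the authors' annotation, the protocadherin group passed (12 of 58 genes, adjusted p = 1.33e-10). The single region in the alpha cluster overlapped the spans of many of its genes, and with regions as units it had 1 of 58 regions (adjusted p = 1).

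Peak lists were longer in the transgenic group, within the spread between animals. The 3 transgenic lists held 105218 ± 22834 peaks (SD, n = 3) and the 3 wild-type lists 67327 ± 40765 peaks (SD, n = 3), with p = 0.20 in a two-sided exact permutation test that cannot go below 0.10 with 3 animals per group. Peaks covered 51.0 ± 14.3 Mb (SD, n = 3) in transgenic and 29.2 ± 23.9 Mb (SD, n = 3) in wild-type lungs (exact permutation p = 0.30). The median peak width was 415 ± 39.9 bp and 332 ± 119 bp (SD, n = 3 each; exact permutation p = 0.40). Wild-type replicate 3 had the shortest list, with 30640 peaks over 6.89 Mb, and transgenic replicate 1 the longest, with 120349 peaks over 63.4 Mb. Of all RefSeq genes, 24.0 ± 5.03% had a peak within 1000 bp of an end in the transgenic lists and 15.1 ± 10.1% in the wild-type lists (SD, n = 3 each; exact permutation p = 0.20). This difference of 8.94 percentage points was 0.607 with an equal number of top-scoring peaks per list (exact permutation p = 0.60), 14.3 without wild-type replicate 2 and 4.31 without wild-type replicate 3. The share of peaks lying at gene ends was 0.892 percentage points higher in the transgenic lists (exact permutation p = 0.40), and 1.54 and 0.139 points higher without wild-type replicates 2 and 3.

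**Figure D4:**
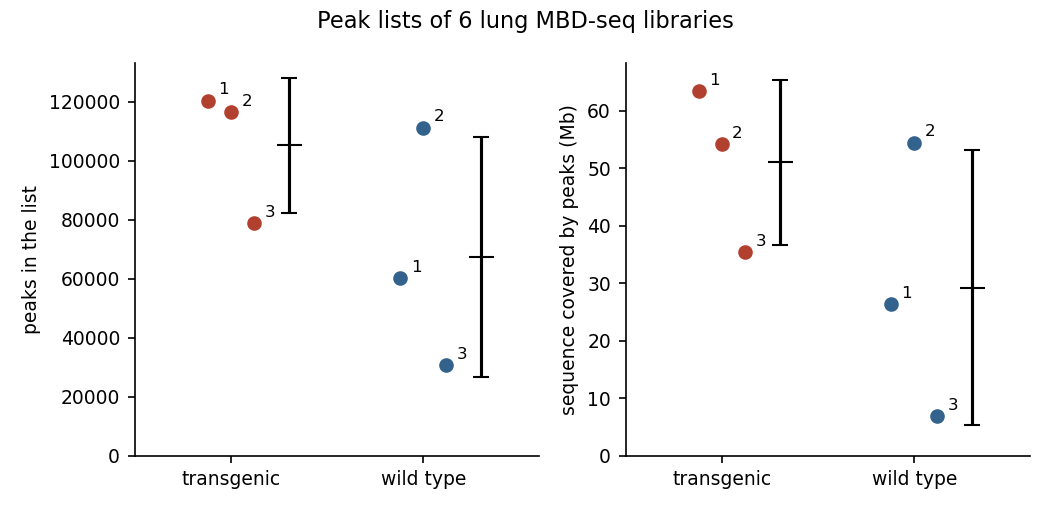
Number of peaks (left) and sequence covered by peaks in Mb (right) in each library, 1 point per animal labelled with its replicate number, with the group mean and SD (n = 3) as black bars. The transgenic lists hold 78952 to 120349 peaks and the wild-type lists 30640 to 111211, so the groups overlap.

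Merging the 6 lists gave 166001 regions. A peak in all 3 transgenic lists and in no wild-type list was found at 2987 regions, and the opposite at 24. Of these, 24 and 9 were also differential regions of the authors' deposited table. With the same number of top-scoring peaks taken from each list the counts were 657 and 161, and without wild-type replicate 2 they were 20319 and 109. Without transgenic replicate 2 or 3 the transgenic-specific count was 5506 or 10211, and the wild-type-specific count was 40 to 868 without any 1 of the 6 libraries. Leaving out a library drops a condition of the definition, so such counts rise by design. By the lowest of the 3 scores, the first transgenic-specific regions at a gene end lay at 1700030C10Rik on chromosome 12 (lowest score 205), Dnmt3b-ps1 (185) and Gm7153 on chromosome X (150). They were followed by Gm51997 on chromosome 12 (126), Spire1, an actin nucleation factor gene, on chromosome 18 (122) and LOC115487393 beside Lrrc20 on chromosome 10 (119). The only wild-type-specific region at a gene end lay at Gm52862 on chromosome 6 (lowest score 53.1). Covered sequence was shared to a mean Jaccard index of 0.362 within groups and 0.344 between groups (one-sided exact permutation p = 0.20 over 10 splits), and the difference turned negative, from -0.0657 to -0.0364, without any single transgenic library. In those cases the within-group mean rests on 1 transgenic pair and the 3 wild-type pairs.

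Among alveolar type 2 markers, the cell type that drives the transgene, Lamp3 had a peak at an end in all 6 libraries. The surfactant genes Sftpb and Sftpd, the lipid transporter gene Abca3 and the lineage factor gene Nkx2-1 had none in any library. Of 40 tumour suppressor genes, Rb1 and Stk11 had a peak at an end in all 6 libraries, while 28, among them Cdkn2a, Apc and Trp53, had none in any library. These genes were chosen after their values were seen. For each gene group fixed in advance, the share of members with a peak at an end was set against all genes of the same library. In none of the 15 groups did the 3 transgenic and 3 wild-type values separate, which chance alone gives for 10% of groups. Imprinted genes had a peak at an end in 66.7 ± 9.55% of members in transgenic and 52.1 ± 23.5% in wild-type lungs (SD, n = 3 each), and germline genes in 91.7% of members in every transgenic list and 83.3 ± 14.4% (SD, n = 3) in wild-type lists. After subtracting all genes, the transgenic minus wild-type difference was 8.30 percentage points for protocadherins, 5.64 for imprinted genes, 3.56 for immune markers, 2.96 for alveolar type 2 markers and 1.58 for lung oncogenes. It was 1.06 for each of the alveolar type 1, endothelial and mesenchymal marker groups. The difference was -0.612 for germline genes, -2.00 for Wnt signalling, -2.28 for tumour suppressors, -2.69 for the methylation machinery, -3.70 for homeobox and T-box genes, -6.73 for olfactory and vomeronasal receptors and -8.94 for airway markers. The smallest two-sided exact permutation p was 0.30 and every adjusted p was 1.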

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

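The alternatives without chromosomes X and Y, regions as units for gene groups and the separate treatment of touching peaks were chosen after seeing the data. All 50 alternatives for the 5 library measures kept the higher transgenic mean, 5 (the replicate block) by construction. The replicate numbers do not pair the animals, since deviations of same-numbered libraries from their group means correlated at -0.0337, 0.0115 and -0.00107 over regions. With the replicate number as a block the difference of 37890 peaks had an exact sign-flip p of 0.25, the smallest that 3 pairs can give. A block keeps each difference and could pass no test. Leaving out each library in turn gave differences of 19547 to 59832 peaks, 10.6 to 34.4 Mb in place of 21.8, 15.2 to 128 bp of width in place of 82.7, 4.31 to 14.3 points of gene ends in place of 8.94 and 0.139 to 1.54 points of peaks at gene ends in place of 0.892, each lowest without wild-type replicate 3 and highest without wild-type replicate 2. With an equal number of top-scoring peaks the differences were 5.66 Mb, 172 bp and 0.607 points of gene ends, and with protein-coding genes alone 0.448 points of peaks at gene ends. Unknown depth limits these comparisons, and no DMR count could be refitted for other splits or left-out libraries, as read counts were not used. CpG content was not run.

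Transgenic-specific and wild-type-specific regions, 2987 and 24 in the main count, numbered 657 and 161 with an equal number of top-scoring peaks, 1797 and 8 with peaks at or above the pooled median score, and 13825 and 1102 with 2 or more libraries of a group. Where a peak had to cover 0.5 or more of the region, wild-type-specific regions numbered 7. Leaving out each library in turn gave 3225 to 20319 and 40 to 868, with over 1.5 times the main count without transgenic replicate 2 or 3 or wild-type replicate 2, and, for wild-type-specific regions, without any library. Leaving out a library, or asking for 2 or more libraries of a group, relaxes the definition, so these counts rise by design. The within minus between group Jaccard difference of 0.0182 ranged from -0.0657 to 0.180 with a library left out, negative without transgenic replicate 1, 2 or 3. The within-group mean then rests on 1 transgenic pair and the 3 wild-type pairs, so these weigh more. Their indices were 0.355, 0.178 and 0.115. For the other changes the cause was not tested.

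At the stricter FDR 151 higher and 38 lower differential regions were left, and 62 higher regions reached an absolute log2 fold of 1, by construction of the thresholds. The share of differential regions whose peak calls differed between groups in the direction of the fold was 36.6%, since 239 of 407 were tied, and it was 81.3% with an overlap of 0.5 or more, 30.7% at the stricter FDR, and 31.2% to 39.6% with a library left out. Without X and Y the higher minus lower difference in the share at transcription starts was -3.18 percentage points (p = 0.236) in place of -7.39 (p = 0.00759), and for CpG islands 4.83 (p = 0.0438) in place of 3.63 (p = 0.129), both by Fisher's exact test. For the overlap and the X and Y alternatives the cause was not tested.

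Of 135 alternatives for gene groups at gene ends, 29 turned the direction of a transgenic minus wild-type difference, none of which passed a test. With an equal number of top-scoring peaks it was 3.10 percentage points for airway, -3.94 for endothelial, -4.77 for immune and -0.607 for mesenchymal markers, 1.06 for tumour suppressors, 4.95 for germline and 1.48 for Wnt genes, and 2 groups separated. With 2000 bp it was -0.173 for alveolar type 2 and -2.08 for endothelial markers and 7.37 for Wnt genes. With a library left out it ranged from -2.47 to 7.71 for alveolar type 2, -5.98 to 5.14 for alveolar type 1, -1.10 to 4.43 for endothelial and -4.33 to 5.69 for mesenchymal markers, -2.18 to 5.05 for oncogenes, -1.71 to 11.7 for imprinted, -4.31 to 4.31 for germline, -1.20 to 16.7 for protocadherin and -8.19 to 4.42 for methylation machinery genes, and 0 to 2 groups separated. The cause was not tested. With the nearest RefSeq gene, 1 group, the protocadherins, passed the test for differential regions by 1 region that overlapped many spans.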

Other observations

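The tests of gene groups, X genes, single-copy Y genes, Dnmt3b, enrichment, list length and splits in this part were chosen after the result was seen, and the test of chromosome Y score percentiles when the share of peaks on chromosome Y was known. Germline genes carried peaks at their ends in lungs of both groups far more often than other genes, in 66.7% to 91.7% of 24 genes per library, above other genes in 6 of 6 libraries (Fisher's exact test in each library, largest adjusted p = 4.58e-10). Dazl, Ddx4, Mael, Sycp1, Sycp3 and Tex19.1, which act in germ cells, had a peak at an end in all 6 libraries, and Stag3 and Dmrtb1 in 0, all chosen after their values were seen, as were the imprinted genes named next. Imprinted genes were above other genes in 6 of 6 libraries, in 9 to 24 of 32 genes (largest adjusted p = 0.000267), with Kcnq1ot1, Peg10, Peg13, Gnas and Zrsr1 covered in all 6. Olfactory and vomeronasal receptor genes were below other genes in 6 of 6 libraries, at 1.49% to 7.53% (largest adjusted p = 7.15e-16), and homeobox and T-box genes were below with an adjusted p under 0.05 in 4 of 6. Clustered protocadherins were above other genes in 5 of 6, with an adjusted p under 0.05 in 3 and shares of 5.17% to 69.0%. The spans of many alpha-cluster genes overlap, so these genes are not independent units, as Fisher's exact test takes them to be. The other 10 groups had no adjusted p under 0.05 in any library.

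Of the 18 differential regions on chromosome Y, 17 were higher in the transgenic mice, and 15 of the 33 on chromosome X were lower. A candidate explanation is that animals of different sex were compared, with transgenic replicates 1 and 3 male and the other 4 animals female, since the inactive X of females is methylated at many gene starts. The X to autosome ratio of gene ends with a peak parted these libraries. The lowest of those 4 was 2.95 times the higher of transgenic replicates 1 and 3. Of 9 single-copy Y genes, 8, 4 and 5 had a peak in transgenic replicates 1, 2 and 3. In wild-type replicates 1, 2 and 3 the counts were 2, 4 and 2. Peaks at these genes numbered 15, 5 and 10 in the transgenic lists and 3, 5 and 3 in the wild-type lists. Transgenic replicates 1 and 3 thus had the most, replicate 3 narrowly by genes (5 against 4), but no library had none. At the 17 higher Y regions the median score percentile of transgenic replicate 2 lay lower, by -39.2 points, than the mean of replicates 1 and 3, which fits more chromosome Y signal in those 2, and of the 15 lower X regions 7, 12 and 2 had a peak in transgenic replicates 1, 2 and 3 and 13, 15 and 6 in the wild-type replicates. Of 15 regions within the single-copy Y genes, 6 had peaks in transgenic replicates 1 and 3 only and 4 in replicate 1 only, which goes with the explanation. What stays open is that 3 of the 15 had peaks in all 6 libraries and that the labels give no sex. An effect of the transgene on these chromosomes, or sex differences on autosomes, were not tested.

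The 2 regions of Dnmt3b-ps1 had peaks in the transgenic libraries only. Longer transgenic lists as the whole cause would give weak peaks there. The lower of the percentiles of the 2 regions' lowest transgenic score was 99.8 among all 2987 transgenic-specific regions. Wild-type replicate 2, with a longer list than transgenic replicate 3 (111211 against 78952 peaks), had neither peak. The regions were chosen for a large fold and for having no wild-type peak, which favours both values, so list length is not ruled out by them. A candidate explanation is that reads of the transgene, a DNMT3B sequence whose species is not given in the sources used here, aligned to Dnmt3b and its copy. It predicts transgenic-only regions within Dnmt3b too, where 1 of 13 regions was of that kind against 1.80% of all regions (one-sided Fisher's exact p = 0.210). With 13 regions this and a gain of methylation at Dnmt3b-ps1 cannot be told apart, and the transgene's sequence was not used here.

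Higher differential regions were strong and wide and lower regions weak and narrow. A candidate explanation is weaker enrichment in the wild-type libraries, which would lower counts at strongly captured regions. The median score of all peaks was 107 ± 18.2 in transgenic and 82.9 ± 17.3 in wild-type lists (SD, n = 3 each; two-sided exact permutation p = 0.20), and the highest wild-type value, 103, lay above the lowest transgenic value, 91.3, so weaker enrichment stays open. Shorter wild-type lists cannot be told apart from it either, since only 4 lower regions had a peak in all 6 lists, where higher regions exceeded lower regions by 1.37 in median log2 concentration (lower 95% bootstrap bound 0.665), against 2.60 over all regions. That goes against list length, and it is left open because of a minimum of 10 regions per direction that was set after the 4 were seen. An effect of the transgene was not tested apart from these.

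The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 3011 group-specific regions and the highest other split 12554, so 2 of the 10 splits gave as many. That other split set transgenic replicates 1 and 2 and wild-type replicate 2, which have the longest lists, against the rest. List length and a structure of these samples cannot be told apart as the cause of its count. With an equal number of top-scoring peaks per list that split was still the highest, with 1029 regions against 818 for the real split, a gap with no spread to judge it by. A region over Gm10925 on chromosome 1 (24613064 to 24615583), chosen after its values were seen, had a log2 fold of -2.35 in the authors' deposited table. It had a peak in transgenic replicate 2 (score 60.4) and in wild-type replicates 1 and 3 (146 and 66.7). Mitochondrial peaks were listed 3 times each in wild-type replicates 2 and 3 and 0 times in the other lists. A link between the region and these peaks was not tested.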
